A study of Homo sapiens with 6 samples.

How the data were processed

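The abundance of sgRNA inserts was measured by amplicon sequencing of genomic DNA from 22Rv1 cells, a human prostate cancer line, that stably expressed dCasRx-METTL3. This protein joins an RNA-targeting Cas13d without nuclease activity to METTL3, the enzyme that writes the m6A methyl mark on RNA. The sgRNAs were designed against m6A peaks in transcripts of prostate and lung cancer. Cells were infected at a multiplicity of about 0.3 and, from 24 h later, selected with blasticidin for 5 days. Libraries came from day 0, after this selection (T0), and from day 16 of further culture (T16), with 3 libraries per time point and a stated coverage of 400 cells per sgRNA. The 6 libraries were grouped by time point as labelled. Libraries with a catalytically inactive METTL3 were not analysed here.

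According to the submitters' processing notes, reads were trimmed with Trim Galore, aligned with Bowtie2 and summarised with MAGeCK on hg38, with no versions stated. The deposited sgRNA table has 12736 entries, and each cell of its count columns holds 3 values, 1 per library, which is a composite unit (other) and not a single number. These values are read counts that the authors divided by a size factor per library. In the deposited columns named as means, the signal was the median of the 3 libraries in 100% of entries and their mean in 2.91% (T0) and 3.51% (T16), within a relative tolerance of 0.001. The authors' sgRNA table also gives a log2 fold change of those medians, a score and a p-value with its false discovery rate (FDR). The authors' target table gives, for 1028 targets, the number of entries, the median log2 fold change and the p-value, FDR and rank from robust rank aggregation, for depletion and for enrichment. The T0 and T16 columns were taken as the control and treatment columns of that table. The 3 values in a cell carry no replicate number, so libraries are named by time point and position. Neither table gives coordinates or sequences, so no genome position is given for any peak. Of the 1024 symbols in the target names, 1011 were current and 10 older symbols in a RefSeq gene table of GRCh38.p14, used for names alone, and 3 had no match.

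Of the 12736 entries, 691 repeated the values of another entry of the same target in all 6 libraries. Each distinct count profile of a target was counted once, which left 12045, the size of the library as described. They comprise 11549 sgRNAs in 1025 gene targets and 496 control sgRNAs in 3 sets (196 named Scramble, 150 gLuc and 150 eGFP). Each target had at least 5 distinct sgRNAs, the median was 5 and the most 300. All values of a library were multiples of a step, and dividing by it gave whole reads, within 0.1 reads, for 100% of sgRNAs. These recovered reads ranged from 9298879 to 14257316 per library over distinct sgRNAs, and from 9556823 to 14654396 over all listed entries. Counting error alone corresponds to an SD of 0.04 in the log2 change of a targeting sgRNA, with reads taken as independent molecules, which they are not. Intervals on shares of sgRNAs are 95% Wilson intervals. They treat sgRNAs as independent, although all share the same 6 libraries.

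Changes between T16 and T0 were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2 of the normalised count plus a pseudocount of 1. Values for a target were the mean of its sgRNAs' log2 values in each library. Tests covered sgRNAs with a mean of at least 20 and targets with at least 3 tested sgRNAs, and neither filter removed any. Benjamini-Hochberg adjusted p-values had a threshold of 0.05. Gene lists with at least 5 measured targets were tested with limma's camera at a preset correlation of 0.01. The lists cover m6A writers, erasers and readers, androgen signalling and prostate lineage, ribosomal proteins and translation factors, splicing and mRNA processing, the proteasome and ubiquitin system, cell cycle and mitosis, DNA replication and repair, chromatin regulators, receptor tyrosine kinase and MAPK signalling, PI3K and mTOR signalling, Wnt signalling, TGF-beta signalling, Hippo and YAP signalling, Notch signalling, p53 signalling and apoptosis, tumour suppressors, oncogenes, transcription machinery, mitochondrial respiration, lipid and sterol metabolism, hypoxia and glycolysis, stress response and immediate early genes, and adhesion and extracellular matrix genes. These lists, the tests named as planned and the naming rule were fixed before the data were examined. The rule names the 12 largest falls and the 12 largest rises among targets past the threshold with at least 2 of every 3 sgRNAs in that direction. It adds the 5 top targets per direction of the authors' table, up to 4 members per list, and the single sgRNAs of the first 3 targets per direction. Some targets under this rule are not reported here.

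Tests across sgRNAs used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The planned ones set the mean log2 change of a target against 100000 random sets of as many sgRNAs matched on abundance, and ran robust rank aggregation of limma statistics with a percentile limit of 0.25. The same test against random sets of control sgRNAs, and one matched on T0 counts, were added after the data had been seen. Random sets were drawn with replacement, and the matched ones could include the target's own sgRNAs. Rank aggregation was set against simulated uniform ranks. Library evenness was compared by an exact two-sided permutation test. The share of sgRNA pairs of a target with the same sign was set against 1000 random regroupings. Overlap with the authors' calls was tested with Fisher's exact test. Alternatives covered the pseudocount, the filter on low counts, 3 other scalings, the variance trend, the median over sgRNAs, leaving out each library, repeated entries kept, and limma-voom on recovered reads.

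The limma fits were tested on simulated data with the sizes of this screen. For T16 against T0 without drift shared by the libraries of a time point, 85.0% of sgRNAs changed by a log2 of 0.5 and 96.0% of targets changed by 0.2 were recovered, and 0.604% of unchanged targets were called. With a shared drift of SD 0.19 per sgRNA, 16.2% of unchanged targets and 21.8% of unchanged sgRNAs were called. Tests across sgRNAs were tried on a smaller simulation of 400 targets, of which 40 changed by a log2 of 0.4. The test against control sets recovered 38 of these 40, the abundance-matched test 31 and rank aggregation 23. In the same order, 3, 2 and 0 of the 360 unchanged targets were called. Adjusted p-values depend on the number of targets and on the share that changed. These counts therefore do not give the recovery to be had among the 1025 gene targets of the screen.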

Results

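In 22Rv1 prostate cancer cells with dCasRx-METTL3, 12045 distinct sgRNAs against m6A peaks of 1025 gene targets and 3 control sets were counted at day 0 (T0) and day 16 (T16). Each time point had 3 libraries. The T0 libraries held 9450801, 10784608 and 9298879 recovered reads, and the T16 libraries 9885265, 9364469 and 14257316. The median sgRNA had between 759 and 1156 reads in a library, and the rarest between 28 and 63. Correlations of log2 counts across sgRNAs, which are not independent replicates, were 0.910 to 0.913 within T0, 0.941 within T16 and 0.856 to 0.863 between the time points. Whether libraries of a time point came from separate cultures is not stated, so p-values of limma fits and library permutations measure only the spread between these samples. Tests that draw, rank or count sgRNAs measure the spread among sgRNAs in these same libraries.

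The first comparison asked which peak-directed sgRNA sets lost or gained abundance during growth. CHD9, a chromatin-remodelling helicase listed as CHD9_peak1, had the largest fall. The geometric mean of its 5 sgRNAs went from 699 normalised counts at T0 to 543 at T16, a log2 change of -0.37 ± 0.05 (SE, n = 3 libraries per time point, adjusted p 0.00754). PRR7, a transmembrane adaptor protein, went from 652 to 508 (-0.36 ± 0.04, adjusted p 0.00754). KLF6, a zinc-finger transcription factor with tumour suppressor activity in prostate cancer, went from 657 to 518 (-0.34 ± 0.05, adjusted p 0.00754). DAAM1, a formin of non-canonical Wnt signalling, had the largest rise, from 781 to 986 (0.34 ± 0.09, adjusted p 0.0408). All 5 sgRNAs of each of these 4 targets moved in the direction of the mean. CHD9, PRR7 and KLF6 stayed past the threshold whichever library was left out, with adjusted p up to 0.0355, whereas DAAM1 did so only without T0 library 2 (adjusted p 0.0287, against up to 0.122 without another library).

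Other rises were those of ZDHHC16, a palmitoyltransferase (0.29 ± 0.04), SLC2A1, the main glucose transporter of many tumours (0.25 ± 0.04), and FAM171B, a membrane protein (0.24 ± 0.04). CAMSAP2 of microtubule minus ends, LSM10 of histone mRNA processing, the receptor kinase MET, the death-receptor adaptor FADD, BLOC1S5 of lysosome-related organelles, the histone methyltransferase NSD1, the antiproliferative BTG2 and the Fanconi anaemia protein FAAP100 rose by log2 values of 0.22 down to 0.19. Falls after KLF6 were those of ZMYND8, a reader of acetylated histones (-0.24 ± 0.04), CGGBP1, a CGG-repeat-binding protein (-0.23 ± 0.06), and KIAA1549, a fusion partner of BRAF in glioma (-0.23 ± 0.04 over 10 sgRNAs). The glucosylceramidase GBA2, the splicing regulator RBM4, the RNA helicase DDX6, the checkpoint protein SFN, the autophagy kinase ULK1 and the phosphatase subunit PPP4R3A followed, with values of -0.22 to -0.19. Of these 24 named targets, 10 were past the threshold whichever library was left out. CGGBP1 and BLOC1S5 were past it in none of these fits, with lowest adjusted p of 0.0503 and 0.0569. Against random sets of as many control sgRNAs, 22 of the 24 had an unadjusted p under 0.05. BTG2 (0.0515) and FAAP100 (0.0566) did not. After adjustment only CHD9 and PRR7 passed in that test, so the other rises and falls rest on the spread between libraries.

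In limma, 56 targets were higher and 54 lower at T16 of the 1028 tested, and 296 had an unadjusted p under 0.05. The share of targets called differed from that of control sgRNAs grouped the same way by less than the SD between regroupings. Random sets of 5 control sgRNAs were called in 14.2% of cases (SD 4.15 over 100 regroupings of 99 sets), against 15.4% of the real targets of 5 sgRNAs (90 of 583). The sets Scramble, gLuc and eGFP as a whole were not called. Centring each library on control sgRNAs gave 31 higher and 87 lower targets, so the share of calls that were higher was 26.3%, against 50.9% with the deposited scaling. The total of 110 went to 52, 43 and 36 without T0 library 1, 2 or 3, and to 19, 27 and 27 without T16 library 1, 2 or 3. With the median over sgRNAs in place of the mean, 41 targets were called, of which 21 were among the 110 and 5 among the 24 named.

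CHD9 and PRR7 were also past the threshold against control sgRNAs, in a test chosen after the data had been seen. The means of random sets of 5 control sgRNAs had an SD of 0.0961 and a 95% range of -0.18 to 0.19. Over targets of all sizes, 54 (5.27%) lay outside the 95% range of control sets of as many sgRNAs. That is near the share that such a range leaves outside by construction. In the test against random control sets, CHD9 and PRR7 each had an adjusted p of 0.0307, KLF6 of 0.0513, DAAM1 of 0.0999 and KIAA1549 of 0.125. The unadjusted p was under 0.05 for 56 of the 1025 targets, in total near the share of 0.05 that chance alone gives. Of these, 17 were higher and 39 lower, an uneven split whose cause was not tested. In the planned test against random sets matched on abundance, 0 targets passed, with 67 at an unadjusted p under 0.05, and the lowest adjusted p was 0.298, that of DAAM1. CHD9 and PRR7 had an adjusted p of 0.558 there. Abundance takes in the T16 counts, and the sets matched to CHD9 and PRR7 had means of -0.038 and -0.044 themselves. Planned rank aggregation of the limma statistics called 0 targets. Its separate one-sided tests had 56 targets for enrichment and 48 for depletion at an unadjusted p under 0.05, 104 in all. Each is near the share of 0.05 that chance alone gives in such a test. CHD9 came first for depletion (rank aggregation, adjusted p 0.113).

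**Figure D1:**
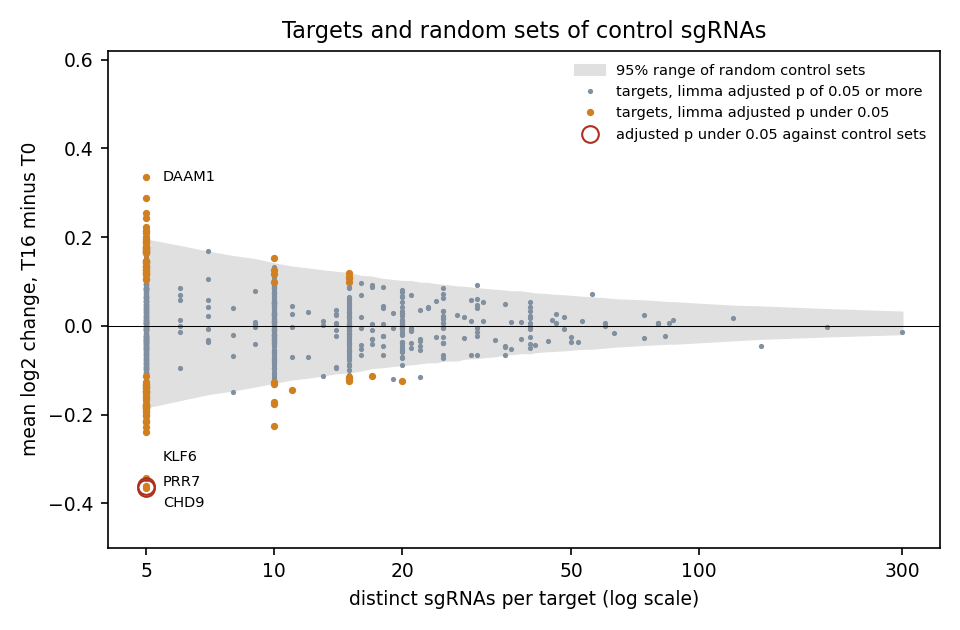
Mean log2 change of each target (T16 minus T0) against its number of distinct sgRNAs on a log scale, with the 95% range of random sets of as many control sgRNAs in grey. CHD9 (-0.37) and PRR7 (-0.36), ringed, had an adjusted p of 0.0307 against control sets.

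Single sgRNAs were compared next, with control sgRNAs as the background. One SLC2A1 sgRNA rose from 510 ± 25.01 to 879 ± 25.17 normalised counts (mean ± SD, n = 3), a log2 change of 0.78 (adjusted p 2.5e-07), while another was at -0.22 (adjusted p 0.156). The strongest KLF6 sgRNA fell from 549 ± 55.1 to 341 ± 42.5 (-0.69, adjusted p 7.3e-05). For CHD9, 3 of 5 sgRNAs fell on their own, by 0.62, 0.52 and 0.47 on the log2 scale, and the weakest was at -0.04 (adjusted p 0.835). For PRR7, 3 of 5 fell, by 0.59, 0.48 and 0.40. For DAAM1, 4 of 5 rose, by 0.30 to 0.55. For ZDHHC16, the strongest of 5 rose by 0.51 (adjusted p 0.00249) and the weakest was at 0.07 (adjusted p 0.65).

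**Figure D2:**
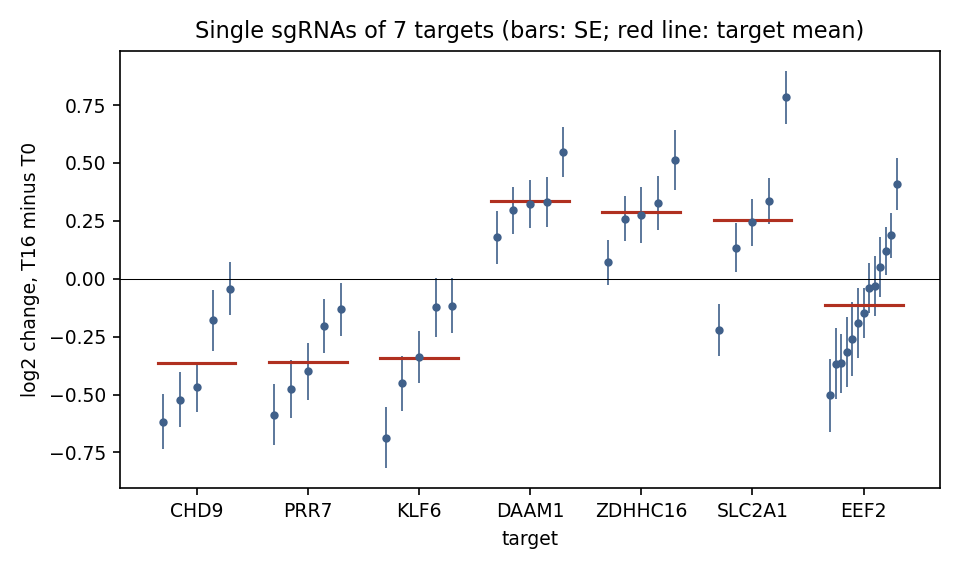
Log2 change (T16 minus T0) of each sgRNA of 7 targets, with SE bars and the target mean as a red line. The sgRNAs of CHD9 lie between -0.62 and -0.04 and those of DAAM1 between 0.18 and 0.55, while those of SLC2A1 and EEF2 lie on both sides of 0.

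Across the library, limma called 1139 sgRNAs higher and 1084 lower of 12045, and 3892 had an unadjusted p under 0.05. Control sgRNAs were called as often as targeting ones. Of 11549 targeting sgRNAs, 2125 were called (18.4%, 95% interval 17.7 to 19.1), and of 496 control sgRNAs, 98 were (19.8%, 16.5 to 23.5; two-sided Fisher's exact test, p 0.442). By set, 41 of 196 Scramble, 30 of 150 gLuc and 27 of 150 eGFP sgRNAs were called. In this order, 20, 23 and 16 of the calls were higher and 21, 7 and 11 lower, so the gLuc calls leaned upward. The SD of the log2 change was 0.2159 for targeting and 0.2153 for control sgRNAs, a ratio of 1.003 (95% bootstrap interval 0.949 to 1.07, permutation p 0.935). The median log2 change of targeting minus control sgRNAs was -0.00799 (permutation p 0.513). The total of 2223 went to 1445, 1317 and 1456 without T16 library 1, 2 or 3, and to 1924, 1752 and 1742 without T0 library 1, 2 or 3. Centring on control sgRNAs moved the share of calls that were higher from 51.2% to 42.2%.

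**Figure D3:**
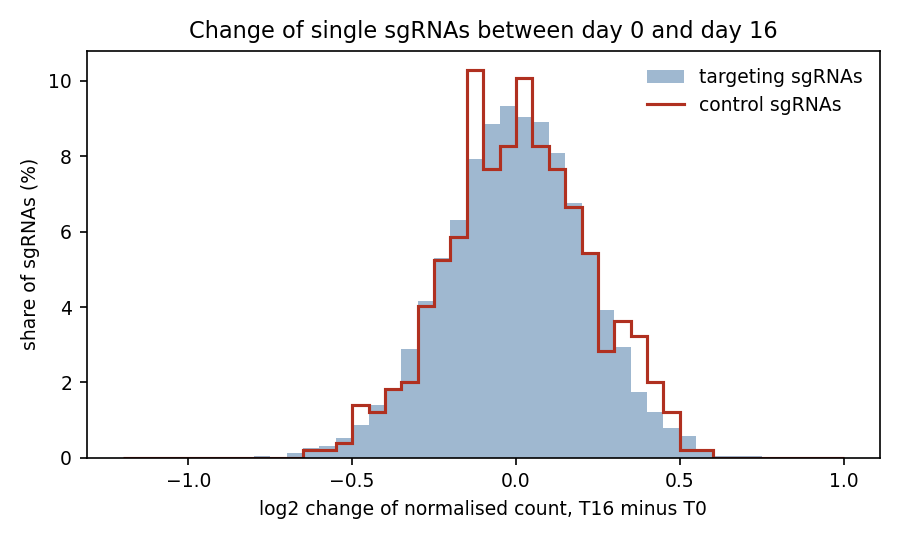
Share of targeting sgRNAs (blue) and control sgRNAs (red line), in percent, by log2 change of the normalised count (T16 minus T0). Both distributions have an SD of 0.22.

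Gene lists fixed beforehand were then compared with all other targets. In p53 signalling and apoptosis, 15 of 22 targets were higher, and FADD, BTG2, the kinase RIPK2 (0.12 ± 0.03) and the adaptor TRAF3 (0.10 ± 0.03) were past the threshold. RIPK2 and TRAF3 were past it in no fit that left out a library, and under control centring 12 of the 22 were higher and 2 called. The 5 Hippo targets were all lower with every scaling, and TEAD4, the transcription factor that pairs with YAP1, came closest (-0.12 ± 0.03, adjusted p 0.0502; limma called 0 of them, with 2 at an unadjusted p under 0.05, and under each of 3 other scalings called TEAD4 alone). Camera gave p 0.0336 for p53 signalling and apoptosis and 0.0297 for Hippo and YAP signalling, with an adjusted p of 0.370 for both. In camera, 0 of 22 lists passed the threshold and 2 had an unadjusted p under 0.05. With an estimated correlation the lowest adjusted p was 0.970, so 0 lists were called under it as well.

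Among the m6A genes, 6 of 7 targets were higher, and the reader YTHDF2 was called (0.11 ± 0.03, adjusted p 0.0497), though under none of 3 other scalings and in no fit that left out a library. In the androgen signalling and prostate lineage list, limma called 0 of 6 targets, with 1 at an unadjusted p under 0.05. Its corepressor NCOR1 was at 0.13 ± 0.05 (adjusted p 0.129). In the lists that follow, higher and lower mark targets that limma called, not every target with that sign. For comparison, limma called 110 of all 1028 targets and 14.2% of random sets of 5 control sgRNAs. Of 21 tumour suppressors, KLF6 was lower, and BTG2, TRAF3, the acetyltransferase CREBBP (0.18 ± 0.04) and the Wnt scaffold AXIN1 (0.14 ± 0.03) were higher. Of 23 oncogenes, MET was higher and UHRF1, a DNA methylation cofactor, lower (-0.18 ± 0.04). UHRF1 was also the 1 call in DNA replication and repair, of 16. Of 39 chromatin regulators, CHD9, CHD7 (-0.15 ± 0.03) and the Polycomb protein CBX8 (-0.13 ± 0.03) were called lower, and CREBBP and NSD1 higher. By sign alone, 18 of the 39 were lower and 21 higher. With the median sgRNA level in each library in place of the mean, CHD7 was at 0.07 and not called. The median of its sgRNA changes was nevertheless -0.18, with 4 of 5 lower.

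In receptor kinase and MAPK signalling, the adaptor GRB10 (0.19 ± 0.03) and MET were among 3 targets called higher, of 16, while 10 had a positive change. In PI3K and mTOR signalling, ULK1 was lower and the mTOR inhibitor DDIT4 higher (0.12 ± 0.03), of 6. In Wnt signalling, DAAM1 and AXIN1 were higher and the cadherin CELSR2 lower (-0.15 ± 0.04), of 10. The corepressor TGIF2 was higher (0.18 ± 0.03), of 7 TGF-beta targets, but its sgRNAs ran from -0.36 to 0.72, with 1 called each way. Those of CELSR2 ran from -0.63 to 0.36, with 1 called each way. Those of NSD1 ran from -0.49 to 0.65, with 2 called higher and 1 lower. The SE over libraries does not hold this spread. In splicing, SNRNP70 of the spliceosome was lower (-0.19 ± 0.03) and the cleavage factor CSTF1 higher (0.15 ± 0.03), of 14. In the ubiquitin list, the ligase adaptor KLHL18 was lower (-0.15 ± 0.03) and the deubiquitinase USP1 higher (0.17 ± 0.04), of 22. In the cell cycle list, the cohesin release factor WAPL (-0.15 ± 0.03) and the elongation cyclin CCNT1 (-0.17 ± 0.04) were lower and the spindle protein ASPM higher (0.13 ± 0.03), of 17. CCNT1 was also the 1 call of 23 in the transcription machinery. In hypoxia and glycolysis, SLC2A1 and DDIT4 were higher and the phosphatase PDP1 lower (-0.16 ± 0.03), of 11. In stress response and immediate early genes, BTG2 was higher and KLF6 lower, of 27. Of these list members, AXIN1, CBX8, CCNT1 and DDIT4 were past the threshold in no fit that left out a library, and ASPM, NSD1, MET, DAAM1, CSTF1, CHD7, USP1, KLHL18, WAPL and CELSR2 in only 1 of 6. Under control centring, AXIN1, DDIT4, NSD1 and ASPM were not called.

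Translation factors (6 targets), mitochondrial respiration (5), lipid and sterol metabolism (6) and adhesion genes (6) had 0 calls in limma, with 1, 2, 0 and 2 targets at an unadjusted p under 0.05. The 4 measured Notch targets were too few for camera and had 0 calls in limma, with 1 at an unadjusted p under 0.05, that of RBPJ, the DNA-binding Notch effector at 0.14 ± 0.04 (adjusted p 0.0765). Over all targets and adjusted over the list alone, the counts were the same in 17 of the 22 lists. Adjusted over the list alone, there was 1 more lower target in receptor kinase signalling (IRS1, 4 instead of 3 calls), in Wnt (CELSR1, 4 instead of 3), in Hippo (TEAD4, 1 instead of 0) and in hypoxia (SLC16A3, 4 instead of 3), and in mitochondrial respiration SCO1 was lower and MFN2 higher, 2 calls instead of 0. For Notch, RBPJ passed adjusted over the list alone (0.0447). The median was above 0 with a mean below 0 for DNA replication and repair, chromatin regulators, oncogenes and the stress list, and the median of each of these was below 0 under rescaling to the same total and under control centring. Camera's direction was down for these except chromatin regulators. For the transcription machinery the mean was above 0 and the median and camera's direction below, and for mitochondrial respiration camera's direction was up with median and mean below 0. The hypoxia median, 0.01, went to -0.01 under control centring.

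The authors' own target table, from the same libraries, was compared with these calls. CHD9 was first for depletion there (FDR 0.00495, median log2 fold change -0.60), followed by the elongation factor EEF2 (FDR 0.126), PRR7 (0.196), KLF6 (0.511) and the long noncoding RNA HEIH (0.764). DAAM1 was first for enrichment (FDR 0.361), and TRAF3, CDR2L and the helicase DDX20 were also among its top 5 (0.455 each). In the limma fit EEF2_peak1 was at -0.11 ± 0.03 (adjusted p 0.0727), HEIH at -0.09 ± 0.03 (adjusted p 0.116), CDR2L at 0.11 ± 0.03 (adjusted p 0.0408, but past the threshold in no fit that left out a library) and DDX20 at -0.0013 ± 0.04 (adjusted p 0.981). EEF2 was listed with 25 entries, of which 13 were distinct. Rank aggregation of the authors' sgRNA p-values gave it a depletion p of 0.00143 with entries as listed and 0.218 with each distinct sgRNA once. At 0.05, the authors' table had 1 target for depletion, shared with the 54 lower here (two-sided Fisher's exact test, p 0.0525), and 0 for enrichment, with 56 at an unadjusted p under 0.05. Of its 61 targets with an unadjusted depletion p under 0.05, 22 were among the 54 lower here (Fisher's exact p 3.89e-15), and of its 56 for enrichment, 23 were among the 56 higher (6.04e-17). Both sets of calls come from the same counts, so this overlap is a check of method and not independent evidence. In the authors' sgRNA table, 14.5% of control and 12.2% of targeting sgRNAs had an FDR under 0.05.

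Evenness of the libraries and agreement within targets described the screen as a whole. The Gini index of the normalised counts was 17.2% ± 0.0437 at T0 and 18.4% ± 0.0665 at T16 (SD, n = 3; two-sided exact permutation p 0.1, the smallest that 3 against 3 can give). The top 1% of sgRNAs held 1.94% and 2.02% of the counts (exact permutation p 0.1), and in each library 0.0083% of sgRNAs lay below 10% of the median. The sgRNAs of a target shared the sign of their change in 50.26% of pairs, against 49.99% ± 0.112 in random regroupings (SD, permutation p 0.015). Without T0 library 3, T16 library 2 or T16 library 3, the share was 50.11%, 50.12% or 50.14% (permutation p 0.132, 0.133 and 0.102). Targets with many sgRNAs give most pairs. With targets weighted equally the share was 50.40% (permutation p 0.149), and for targets of 5 sgRNAs 50.53% (permutation p 0.223).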

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

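The settings chosen only after the result was seen were repeated entries kept or summed, limma-voom on recovered reads, sets of control sgRNAs, sets matched on T0 counts, rank aggregation of the authors' sgRNA p-values, targets weighted equally and targets of 5 sgRNAs. The cause was not tested for any of the changed results unless stated. With other pseudocounts, filters, scalings and variance trends, repeated entries kept, or limma-voom, between 1982 and 2301 sgRNAs and between 110 and 119 targets were called. The authors' sgRNA FDR called 1479 sgRNAs. Leaving out a library, named by its position in the cell, gave 1317 to 1924 sgRNAs and 19 to 52 targets, from fewer samples. The median over sgRNAs was taken over their levels in each library, so it can fall on different sgRNAs at T0 and T16. It called 41 targets, of which 21 were among the 110, and put CHD7 at 0.0658 (limma adjusted p 0.686) instead of -0.15. The median of the CHD7 sgRNA changes was -0.18, with 4 of 5 lower. Among tests across sgRNAs, planned rank aggregation called 0 targets, sets matched on abundance 0, sets of control sgRNAs 2, sets matched on T0 counts 0, and rank aggregation of the authors' p-values 1 with entries as listed and 1 with distinct sgRNAs. These set a target against the spread among sgRNAs, which the limma fit does not hold. Among the 24 largest falls and rises, no sign changed in any setting, 22 passed with control centring, 5 with the median over sgRNAs, and 12 to 19 with a library left out. Over all named targets and settings, 1833 values kept direction and side of the threshold, 488 fell short of it, 24 newly passed it and 1 changed sign (CHD7). The number of lists past the threshold was 0 in each setting, with the lowest adjusted p from 0.272 to 0.970. Sharing of signs within targets ranged from 50.11% to 50.30% with a library left out, and was 50.40% (permutation p 0.149) with targets weighted equally and 50.53% (permutation p 0.223) for targets of 5 sgRNAs. The Gini difference of 1.25 points became 1.34 with the counts of repeated entries summed, and was 1.21 to 1.27 with a library left out. The overlap with the authors' depletion calls was 1 target at 0.05 and at 0.1, and the control SD was 0.215 after rescaling to the same total as before. No filter and 2 or more sgRNAs per target left the same features as the filters used, since each sgRNA had a mean of at least 20. No paired analysis was possible because the 3 values of a cell carry no replicate number; deviations at the same position correlated at 0.00804, 0.00222 and 0.0138 between the time points. The planned edgeR and DESeq2 alternative was not run; limma-voom on the recovered reads was the only count-based fit, with 2282 sgRNAs called. Depth limits little: counting gave an SD of 0.04 against a library spread of 0.11.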

Other observations

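Tests chosen only after the result was seen were those of the spread of sgRNAs, of sets of control sgRNAs and sets matched on T0 counts, of chance among the targets, of rank aggregation of the authors' p-values, of the counts of repeated entries and the rank of EEF2, of neighbouring sgRNAs and of other splits of the libraries. The limma fits and rank aggregation of their statistics were planned.

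Some members of the gene lists, picked after their values were seen, had a limma adjusted p between 0.05 and 0.1. TRIB3, a stress-induced pseudokinase, was at -0.10 ± 0.03 (SE, n = 3) with 12 of 15 sgRNAs lower (adjusted p 0.0943), and the immediate early gene IER2 at -0.11 ± 0.03 with 9 of 15 lower (adjusted p 0.066). The lactate exporter SLC16A3 was at -0.09 ± 0.03 with 7 of 10 lower (adjusted p 0.0868), opposite in sign to the glucose transporter SLC2A1.

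The spread of log2 changes went beyond the libraries of a time point, in control as in targeting sgRNAs. The spread within time points accounts for an SD of 0.11 of the total of 0.22, which leaves 0.186 for targeting and 0.185 for control sgRNAs. Counting of reads gave an SD of 0.0429, too little by far, and the SD ratio of targeting over control sgRNAs, 1.003 with an upper bound of 1.07, argues against effects on targets as the main source. Sampling of cells between T0 and T16 would, as the only source, give a variance that falls as 1 over abundance, a log-log slope of -1. The slope of the remaining variance was -0.72 (95% interval -0.84 to -0.58), which excludes -1, against -0.94 in controls (-1.68 to -0.35), which does not. Sampling may still contribute beside a source that depends less on abundance, and whether either arose in culture, at DNA input or at PCR was not tested, so limma calls of targets may largely reflect drift shared by the libraries of a time point.

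CHD9 and PRR7 are the targets that stood out most from control sets. The falls as such did not rest on 1 outlying sgRNA. Leaving out any 1 sgRNA kept the unadjusted p against control sets at 0.00362 or lower, with remaining means of -0.45 to -0.30. Both targets were picked for their falls in these same sgRNAs, so that p cannot decide whether 1 sgRNA made them stand out. Adjustment over all targets was not repeated with an sgRNA left out. In the full test, ZDHHC16 had a lower unadjusted p, 0.00268, and an adjusted p of 0.458. The calls of CHD9 and PRR7 may therefore depend on their strongest sgRNA. A wider spread at low counts stays open: random sets matched on T0 counts had an SD of 0.102 for CHD9 and 0.106 for PRR7, against 0.0961 for control sets, and with log2 changes of -0.37 and -0.36 as before, the adjusted p of both went from 0.0307 to 0.209, so the calls ended, though the unadjusted p stayed at 0.00032 and 0.00052. Neither target had repeated entries. Chance among over 1000 targets stays open too, since planned rank aggregation gave an adjusted p of 0.113 for CHD9 and 0.929 for PRR7, though rank aggregation of the authors' sgRNA p-values gave CHD9 0.0206 with distinct sgRNAs (PRR7 0.416), so a fitness effect of writing m6A on either transcript is a hypothesis that no methylation or expression value was used here to test.

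Repeated entries in the sgRNA table are consistent with reads of 1 sgRNA divided over its entries. The median T0 count was 429 for the 597 sgRNAs listed 2 times and 863 for the 11403 listed once, a ratio of 0.497 (95% interval 0.481 to 0.511), with 0.311 and 0.268 for those listed 3 and 4 times. That these sgRNAs were simply rarer in the cells is argued against by their spread: the variance beyond libraries was 0.573 of that of sgRNAs listed once at the same count (0.457 to 0.700), and 1.08 of that of sgRNAs with the count of both entries together (0.866 to 1.33). Repeats may also have raised EEF2 to the second rank of the authors' depletion table, since its rank aggregation p was 0.00143 with 25 entries and 0.218 with 13 distinct sgRNAs. Of these 13, the 8 listed more than once had a mean log2 change of -0.25 and the 5 listed once 0.11, a contrast whose cause was not tested.

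A further hypothesis, that sgRNAs next to each other in the listing of a target move alike, was not borne out: their correlation across 10522 pairs was 0.0042 (permutation p 0.398, SD of shuffled orders 0.00862). The listing order is not known to follow position in the transcript. The 6 libraries form only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2223 sgRNAs and 110 targets, and the highest of the others gave 0 of each, so that 1 of 10 splits reached each count. For gene lists the real split gave 0 and the highest other 0, so all 10 of 10 were equal.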
